A study of Homo sapiens with 10 samples.

How the data were processed

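Polyadenylated RNA was sequenced from 10 samples of human cells, 5 of infrapatellar fat pad stem cells (IPFSCs) and 5 of nucleus pulposus stem or progenitor cells (NPSCs). Cells at passage 5, other than the untransduced controls, received a lentivirus and puromycin selection, per the labels' protocols, and libraries came from a KAPA mRNA HyperPrep kit. Subread, featureCounts and the genome build hg38 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here.

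The deposited table holds 20468 genes in 10 columns, 1 per library, and all columns were matched to a library by name. The authors deposited log2 values of RPKM (reads normalised by gene length and by the counted reads of the library). The log base, the 1 added before the logarithm and an offset of 0.0001 after it were read from the deposited log2 values, since no label states them. RPKM was obtained by undoing these steps. No further scaling was applied for the main results.

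The depth of each library was recovered from the same values. All 17805 genes with a read came out as whole reads in every library, within a tolerance of 0.002 of a read, and 2663 genes had no read. For 500 drawn genes, 100% were whole with the recovered depths and 0% with depths off by about 1 percent. The recovered depths ran from 12492745 to 16073472 counted reads. Recovered reads served for the depth, the shares and numbers of genes per library, the reads of low genes, the thinning of a library, the simulations and voom as an alternative, and not for the main tests. Gene IDs were looked up in a RefSeq gene table, where 20407 matched.

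Groups were taken from the labels: cell type and treatment, where treatment is untransduced (Ctrl), a GFP lentivirus (GFP), a lentivirus with Cas9 and a guide RNA against HSPG2 (knockout, KO) or a lentivirus with HSPG2 (overexpression, OE). Each cell type has 1 Ctrl, 1 GFP, 2 KO and 1 OE library. The labels do not say whether the KO libraries are separate cultures or guides, nor how many donors gave cells, so p-values measure only the spread between these samples, which may be technical. The mean level of sex-linked transcripts in each library was set against the medians of the other libraries of each cell type. By this measure, 0 of 10 libraries lay nearer to the other cell type. No donor label was used, so the check shows only that libraries of a cell type resemble each other in these transcripts. This check says nothing about treatment.

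Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend in the prior variance, for the 11894 genes with an RPKM of at least 1 in at least 2 libraries. A fold change on this scale understates the change of low genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold, separately in each of 7 comparisons. NPSC against IPFSC, KO against GFP, OE against GFP and GFP against Ctrl in both cell types came from an additive fit of cell type and treatment with 5 residual degrees of freedom. KO against GFP within each cell type, and the difference between these effects, came from a fit with 8 groups and 2 residual degrees of freedom, both from the KO pairs, so the spread of those pairs stands for that of every group. OE against GFP within a cell type is 1 library against 1 and was not tested, since its spread would come wholly from the KO pairs.

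The comparisons, the tests, 32 gene lists and the rule for naming genes were chosen before the data were examined. The rule names HSPG2, the 10 highest and 10 lowest log2 fold changes past the threshold with a mean RPKM of at least 5, or the 5 lowest p-values in each direction where none passed, and up to 4 members of each list past the threshold (2 where none passed). For a single-library difference it names the 10 highest and 10 lowest of at least 1 in size. Sex-linked genes of the Y chromosome, XIST, TSIX, pseudogenes and genes known only by a clone or locus name were left out of naming and stay in the counts. The 28 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals. The second form rests on 5 or 2 residual degrees of freedom and has little power. A list that fails it is therefore not shown to be unchanged. For the single-library differences, a list's median was placed among the medians of 10000 random lists matched on mean expression. Random lists treat genes as independent. A list whose genes move together can therefore reach an extreme percentile through any deviation of 1 library.

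Each test was run on simulated reads with 200 genes changed by known folds, with the gene-wise spread limma estimated. A first version with a single spread for all genes recovered more and was replaced, after its result was seen, because real genes differ in spread. For IPFSC KO against GFP, 44.8% of genes changed by 1.5-fold, 85.1% of those changed by 2-fold and 97% of those changed by 4-fold were called, with 16 unchanged genes called among 12031 tested. For NPSC KO against GFP the shares were 34.3%, 88.1% and 95.5% among 12001 genes tested. They were lower for KO in both cell types (23.9%, 56.7% and 86.4%), for the KO difference between cell types (3%, 40.3% and 93.9%) and for GFP against Ctrl (10.4%, 49.3% and 89.4%). OE in both cell types had 76.1%, 92.5% and 95.5%, and NPSC against IPFSC 94%, 100% and 100%, both simulated without the measured difference of the OE libraries and so too high for the real data. With the OE libraries simulated at the control level, KO in both cell types had 79.1%, 98.5% and 98.5%. A run added after the first result was seen had 9 changed genes in each of 20 simulations. Its 2-fold share was 25% in IPFSCs and 26.7% in NPSCs among 12013 genes tested. False calls were not counted in that run.

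Alternatives were a pseudocount of 0.1, no filter on low genes, median-ratio scaling of the libraries, no intensity trend, the mean of GFP and Ctrl as the control, Ctrl and GFP as 2 libraries of a single control group, the other of both designs, a term for the number in the KO labels, and each library left out in turn. Added after the data had been seen were limma voom on the recovered reads, list tests without the IPFSC OE library, and another pseudocount and scaling for the single-library differences. Gene expression was the only measurement analysed; epigenetic marks, named in the series title, were not analysed here.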

Results

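RNA sequencing measured gene expression in 10 libraries of human mesenchymal progenitor cells in which HSPG2, the gene of the basement membrane heparan sulfate proteoglycan perlecan, was knocked out or overexpressed. IPFSCs come from the fat pad below the kneecap and NPSCs from the gel core of the intervertebral disc. The series title asks for the role of perlecan in the regeneration of mesenchymal tissues. Counted reads per library ranged from 12492745 (IPFSC OE) to 16073472 (NPSC GFP), and 15307 to 16112 genes had a read. Mitochondrial transcripts took 4.9% to 8.4% of the reads. Error on a level is the SD over libraries of a group, and Ctrl, GFP and OE have 1 library in each cell type.

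HSPG2 was lowest in all 4 KO libraries and highest in both OE libraries of its cell type. HSPG2 lies on chromosome 1 from 21822245 to 21937297 on the minus strand of GRCh38. In IPFSCs its RPKM was 54.4 in Ctrl and 55.8 in GFP, 17.9 and 16.7 in the KO libraries (32.2% and 30% of GFP) and 116 in OE, 2.08-fold of GFP. In NPSCs it was 51.8 in Ctrl and 52.3 in GFP, 20.9 and 17.7 in the KO libraries (39.9% and 33.7% of GFP) and 79.9 in OE, 1.53-fold of GFP. Reads on the gene do not tell an intact transcript from one with a disrupted coding sequence. Likewise, they do not tell the transgene from the resident gene.

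**Figure D1:**
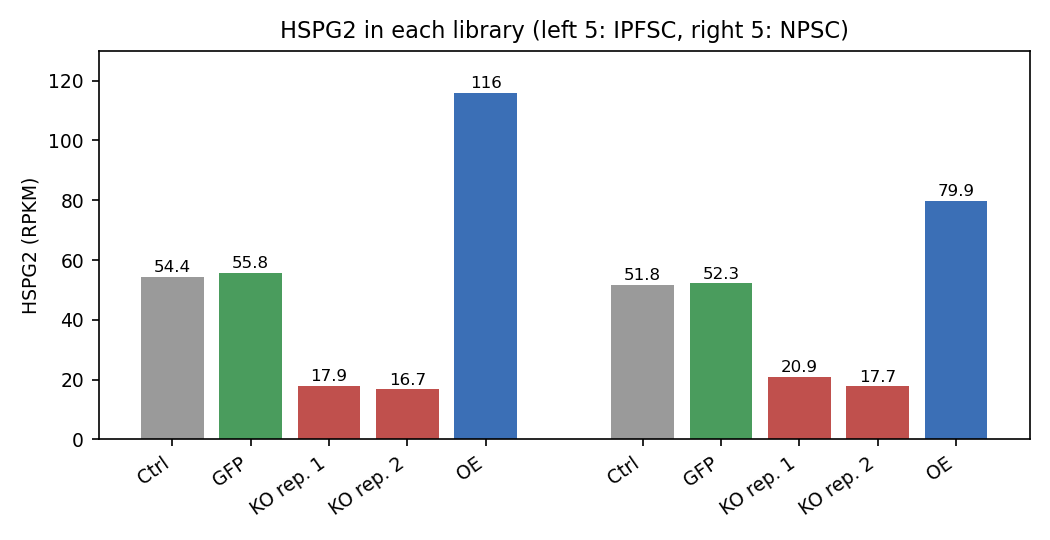
HSPG2 level (RPKM, linear axis from 0) in each of the 10 libraries, 1 bar per library, IPFSCs at the left and NPSCs at the right. The KO bars lie between 16.7 and 20.9, the Ctrl and GFP bars between 51.8 and 55.8, and the OE bars at 116 and 79.9.

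The comparison of cell types asks how NPSCs and IPFSCs differ whatever the treatment. POSTN, a matricellular protein of fibrous connective tissue, had an RPKM of 1680 ± 200 in NPSCs and 215 ± 414 in IPFSCs (SD, n = 5 each), a log2 fold change of 4.92 (SE 0.87, adjusted p = 0.00158). KRT18, a keratin used as a marker of notochord and nucleus pulposus cells, was higher in NPSCs by 4.24 (SE 0.69, adjusted p = 0.00107), at 202 ± 23.1 against 26.7 ± 48.1. Most of both IPFSC means comes from the OE library, with POSTN at 955 and KRT18 at 113 there against 20.8 and 4.08 in GFP. The highest fold change was that of the carboxypeptidase gene CPA4 (6.09, SE 0.40). The smooth muscle actin gene ACTG2 (4.75, SE 0.12), the sodium channel gene SCN9A (4.76, SE 0.08) and the cartilage collagen gene COL11A1 (4.19, SE 0.30) were also higher in NPSCs. The lowest fold changes were those of CHI3L1, a secreted chitinase-like glycoprotein (-8.79, SE 0.31), and PRG4, which encodes the joint lubricant lubricin (-7.91, SE 0.61, RPKM 0.597 ± 0.193 in NPSCs and 530 ± 281 in IPFSCs).

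Of the 11894 genes tested, 8168 passed the threshold, 4624 higher in NPSCs and 3544 lower, and 927 and 1065 of these differed by at least 2-fold. HSPG2 itself did not pass (-0.08, SE 0.11, adjusted p = 0.516). With median-ratio scaling 3895 genes were higher and 4288 lower, a share of higher genes of 47.6% in place of 56.6%. Without the IPFSC OE library, 8134 of the 8155 called genes still tested were called in the same direction. The cell types differ in tissue and stage of development, and cell type and donor cannot be told apart here.

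All 40 measured cell cycle genes were higher in NPSCs, with a median of 2.42, among them the ribonucleotide reductase subunit gene RRM2 (3.58, SE 0.16), the mitotic activator gene CDC20 (3.50, SE 0.22) and MKI67 (3.30, SE 0.17). The list passed camera (adjusted p = 7.7e-13), with adjusted p = 0.28 with an estimated correlation. Of 24 YAP targets and contractile genes, 19 were higher in NPSCs and 5 did not pass, with TPM1 at 3.01 and TAGLN at 2.80 as examples (adjusted p = 0.00099, and adjusted p = 0.41 with an estimated correlation). HOX genes of paralog groups 1 to 8, which pattern the body axis, had 15 of 21 members higher and 3 lower, HOXB7 at 3.59 and HOXD8 at -2.20 (adjusted p = 0.0076, and adjusted p = 0.25 with an estimated correlation). Nucleus pulposus and notochord markers went both ways, 9 of 14 higher and 3 lower (adjusted p = 0.31), with CDH2 at 2.50 and CA12 at -3.28.

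Genes of defence and inflammation were lower in NPSCs. Of 30 interferon response genes, 29 were lower and 1 did not pass, TRIM22 at -2.64 (SE 0.14) and IFI6 at -2.18 (SE 0.16), with adjusted p = 8.8e-09 for the list and adjusted p = 0.25 with an estimated correlation. Of 31 inflammatory cytokines and NF-kB targets, 24 were lower and 4 higher: the neutrophil chemokine gene CXCL6 stood at -7.00 (SE 0.78), the prostaglandin E synthase gene PTGES at -6.02 (SE 0.23) and the complement gene C3 at -5.28 (SE 0.20). This list had adjusted p = 4.7e-06, and adjusted p = 0.23 with an estimated correlation. FGF signalling genes were mostly lower, 14 of 23 against 3 higher, with FGF7 at -6.56 and FGF10 at -3.50 (adjusted p = 0.004, and adjusted p = 0.25 with an estimated correlation). Macrophage and leukocyte markers numbered 3 measured genes, all lower in NPSCs, CD68 at -3.35 and CD14 at -0.93, too few for a list test.

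Lineage and matrix genes were divided between the cell types. Of 16 adipogenic genes, 12 were lower in NPSCs and 3 higher (3 and 13 when adjusted over the list alone), with ADIRF at -3.48 and EBF2 at -3.31 (adjusted p = 0.0076, and adjusted p = 0.41 with an estimated correlation). Cartilage genes split 6 higher to 8 lower (adjusted p = 0.31), and basement membrane genes other than HSPG2 split 11 to 9 of 24 (adjusted p = 0.96). In that basement membrane list, the collagen IV genes COL4A1 (3.21, SE 0.21) and COL4A2 (2.24, SE 0.12) were higher in NPSCs and the laminin gene LAMA3 (-3.96, SE 0.38) lower. Fibrillar collagens and small proteoglycans had 14 of 36 higher and 10 lower (17 and 11 when adjusted over the list alone), with FBN2 at 3.74 and TNXB at -5.42. Matrix proteases and their inhibitors were mostly lower, 15 of 25 against 7 higher, TIMP3 at -4.89 (46.3 ± 4.47 against 1430 ± 374 RPKM), with adjusted p = 0.013 and adjusted p = 0.23 with an estimated correlation.

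**Figure D2:**
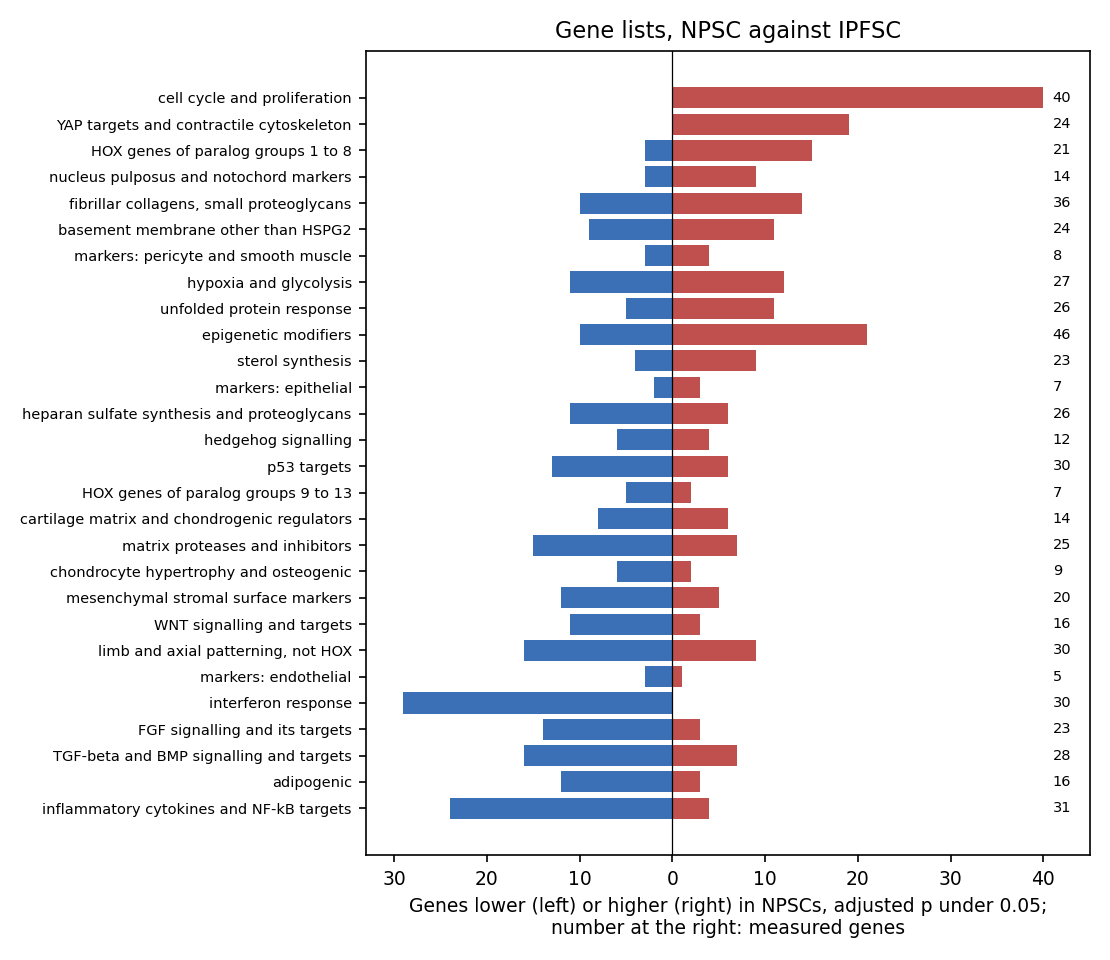
Number of genes of each list that were higher (right) or lower (left) in NPSCs than in IPFSCs at an adjusted p under 0.05, with the number measured at the right edge. Cell cycle genes lie wholly to the right (40 of 40) and interferon genes to the left (29 of 30).

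The KO comparison asks which genes differ between the HSPG2 KO and GFP libraries in both cell types. No library has Cas9 with a guide against another target. Effects of Cas9 and its guide therefore cannot be told apart from the loss of HSPG2, here and within each cell type. HSPG2 was lower in KO by 1.52 on the log2 scale (log2 fold change -1.52, SE 0.15, 18.3 against 54.1 RPKM), in 4 of 4 libraries, with adjusted p = 0.132. Other genes with the lowest p did not pass either: the mitochondrial transfer RNA genes trnM (0.61) and trnI (0.66), the respiratory chain gene NDUFA4L2 (0.39) and the kinase subunit gene CSNK2A2 (-0.22). No gene passed in limma (0 of 11894), 118 had an unadjusted p under 0.05, and limma voom on recovered reads also called 0. HSPG2 passed without the IPFSC OE library (adjusted p = 0.000221, 1 gene called), without the NPSC OE library (0.000235, 1 gene), with the mean of GFP and Ctrl as control (0.0336) and with the 8-group fit (0.00391). Hypoxia and glycolysis genes (median 0.09, adjusted p = 0.018) and p53 targets (median 0.06, adjusted p = 0.026) passed camera upward with no member past the threshold, and both had adjusted p = 0.96 with an estimated correlation. Neither list passed in both cell types: p53 targets had medians of 0.12 in IPFSCs (adjusted p = 0.035) and 0 in NPSCs (0.3), and hypoxia genes 0.06 (0.47) and 0.11 (3.9e-06).

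In IPFSCs, HSPG2 fell by 1.63 (log2, SE 0.11, adjusted p = 0.0218), and the imprinted gene MEST fell by 0.89 (SE 0.06, adjusted p = 0.0218, RPKM 11.5 in KO against 22 in GFP). P4HA3, a subunit of the collagen prolyl hydroxylase, rose by 1.04 (SE 0.09, adjusted p = 0.047, 38.7 against 18.3). Both KO libraries moved the same way for each. The fourth of the 4 genes past the threshold, the selenocysteine transfer RNA gene TRU-TCA2-1, had 0 reads in both KO libraries and 2 in GFP, which is under the floor of 3 reads and allows no fold. The elastin gene ELN stood at 0.80 (adjusted p = 0.0862), the smooth muscle gene LMOD1 at -0.71 and the WNT antagonist gene SFRP4 at -0.85 without passing. These 3 genes passed in limma voom, which called 40 genes (adjusted p = 0.0103 each), and with either use of Ctrl as a further control. Adjusted over the list alone, 6 of 28 TGF-beta and BMP genes were higher and 2 lower, and 2 of 16 WNT genes were higher and 2 lower. Neither list passed camera (adjusted p = 0.35 each). Of 31 inflammatory genes, 1 was higher and 4 lower when adjusted over the list alone, with a camera adjusted p of 0.92. Sterol synthesis genes had a median of 0.17 and passed camera upward (adjusted p = 0.00062), cell cycle genes had a median of -0.08 (adjusted p = 0.023) and p53 targets of 0.12 (adjusted p = 0.035), and each had adjusted p = 0.97 with an estimated correlation. The number of genes past the threshold depended on single libraries: 42 without IPFSC KO replicate 1, 0 without IPFSC KO replicate 2, 2 without IPFSC Ctrl and 11 without NPSC KO replicate 2. Without the filter on low genes or without the intensity trend, HSPG2, MEST and P4HA3 all failed to pass and TRU-TCA2-1 was the 1 gene left. Without IPFSC KO replicate 2 the adjusted p was 0.185 for HSPG2, 0.116 for MEST and 0.281 for P4HA3, and without IPFSC Ctrl it was 0.0624 for P4HA3.

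In NPSCs, HSPG2 differed by -1.40 (SE 0.11, adjusted p = 0.0614). The lipoprotein lipase inhibitor gene ANGPTL4 stood at 0.92 (SE 0.09, adjusted p = 0.11, 3.36 against 1.30 RPKM) and the hyaluronan-binding TNFAIP6 at -0.70 (SE 0.08, adjusted p = 0.112). The microfibril gene MFAP4 stood at -0.62 (adjusted p = 0.185) and the neurofilament gene NEFM at 1.01 (adjusted p = 0.112). ANGPTL4 (0.96) and NEFM (1.08) passed with the mean of GFP and Ctrl as control. With a pseudocount of 0.1, ANGPTL4 (1.3) and TNFAIP6 (-1.12) passed, and MFAP4 passed with neither setting. No gene passed in limma (0), 449 had an unadjusted p under 0.05, and voom called 1, HSPG2. Hypoxia and glycolysis genes passed camera upward (median 0.11, adjusted p = 3.9e-06) and fibrillar collagens and small proteoglycans downward (median -0.16, adjusted p = 8.4e-05), and pericyte and smooth muscle markers upward (median 0.10, adjusted p = 0.021), each with adjusted p = 0.79 with an estimated correlation. Adjusted over the list alone, 1 of 27 hypoxia genes was higher (ANGPTL4) and 1 of 36 fibrillar genes lower. The hypoxia, fibrillar and pericyte lists moved the same way in NPSC OE minus GFP, with medians of 0.03, -0.16 and 0.16. The fibrillar list had a median of 0.06 in GFP minus Ctrl, so the single GFP library could give part of its shift. HSPG2 and 1 further gene passed without either KO replicate (2 genes each, adjusted p of HSPG2 0.003 without replicate 1 and 0.00622 without replicate 2), and with median-ratio scaling HSPG2 passed alone (0.0314).

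Whether the KO effect differs between the cell types was tested directly. P4HA3 differed most (NPSC minus IPFSC -1.35, SE 0.13, adjusted p = 0.297), with -0.31 in NPSCs, where its level was low, against 1.04 in IPFSCs. MEST differed by 0.78 (SE 0.09, adjusted p = 0.297), with -0.11 in NPSCs against -0.89. MFAP4 differed by -0.77 and LMOD1 by 1.01 (adjusted p = 0.385 and 0.297). HSPG2 differed by 0.23 (SE 0.15, adjusted p = 0.999). No gene passed in limma (0), 603 had an unadjusted p under 0.05, and voom called 0. Sterol synthesis genes passed camera downward (median -0.16, adjusted p = 5.9e-05), as did fibrillar genes (median -0.21, adjusted p = 0.00022), while cell cycle genes (median 0.09, adjusted p = 0.0095) and pericyte and smooth muscle markers (median 0.21, adjusted p = 0.025) passed upward, all with adjusted p = 0.95 with an estimated correlation. Across 11894 genes, which are not independent replicates, the KO effects of the cell types had a Pearson r of 0.12 and a Spearman rho of 0.12, with no library shared, and an r of 0.04 with Ctrl in place of GFP as the control.

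The OE comparison asks which genes follow a gain of HSPG2. HSPG2 stood at 0.82 over both cell types (SE 0.17, adjusted p = 0.182), at 0.54 without the IPFSC OE library (adjusted p = 0.131) and at 1.11 without the NPSC OE library (adjusted p = 5.55e-05). The 8-group fit, where HSPG2 passed, has 1 OE and 1 GFP library in each cell type and takes its spread wholly from the KO pairs. Its calls are therefore not a replicated result. The collagenase gene MMP1 (1.29, SE 0.19), the Notch ligand gene DNER (1.83, SE 0.28), the complement protease gene C1R (-1.62, SE 0.20) and the adhesion molecule gene VCAM1 (-1.85, SE 0.26) had the same adjusted p of 0.182. No gene passed in limma (0), 3211 had an unadjusted p under 0.05, and voom called 325. Without the IPFSC OE library 36 genes passed and without the NPSC OE library 7793, but each of these fits has a single OE library, whose spread is taken from the other groups. YAP targets and contractile genes passed camera upward (median 0.81, adjusted p = 3.5e-07, and 0.0058 without the IPFSC OE library), cell cycle genes upward (adjusted p = 0.00027, and 0.26 without it) and interferon genes downward (adjusted p = 0.021, and 0.0037 without it). All had adjusted p = 0.67 with an estimated correlation.

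In IPFSCs the OE library differed from GFP by at least 1 (log2) in 1274 of 7733 genes with an RPKM of at least 5, 480 higher and 794 lower, with no replicate check. The excess of lower genes may depend on the scaling, since median-ratio scaling moved the median over all genes from -0.18 to -0.04. The GFP and Ctrl libraries differed in 1 gene in IPFSCs. The basal keratin gene KRT14 was at 235 RPKM against 1.06 in GFP (6.84), POSTN at 955 against 20.8 (5.45) and the YAP target gene ANKRD1 at 55.2 against 0.423 (5.30). KRT18 (4.49), the tissue factor gene F3 (4.28) and the sialomucin gene PODXL (4.12) were also higher. STEAP4, a metalloreductase, was at 0.455 against 55.9 (-5.29), the pyruvate dehydrogenase kinase gene PDK4 at 1.25 against 83.4 (-5.23), the WNT antagonist gene SFRP1 at 0.771 against 63.4 (-5.18) and CXCL6 at 19.8 against 734 (-5.14).

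By list, 15 of 24 YAP targets and contractile genes were at least 1 higher and 1 lower in IPFSC OE (median 1.5, percentile 100 of 10000 random lists), with TAGLN at 3.81 and CTGF at 2.18. Epithelial markers had a median of 2.15, cell cycle genes of 0.58 and fibrillar genes of 0.42 (13 at least 1 higher and 5 lower, ELN at 4.00 and LOX at 3.06), each at percentile 100. Medians were -0.93 for adipogenic genes, -0.71 for interferon genes and -0.65 for inflammatory genes, each at percentile 0, with CEBPD at -3.16, STAT2 at -1.46 and CXCL12 at -3.42. The median over all genes was -0.18, and -0.04 with median-ratio scaling. Of the lists with at least 5 genes, hypertrophy and unfolded protein response genes changed sign with that scaling (-0.06 to 0.03 and -0.12 to 0.04).

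In NPSCs the OE library differed from GFP by at least 1 in 33 of 7371 genes, 12 higher and 21 lower, with no replicate check. DNER was at 19.2 RPKM against 7.28 (1.29), MMP1 at 68.1 against 29.1 (1.20) and KRT19 at 40.2 against 14.6 (1.40). COL14A1 was at 2.18 against 10.5 (-1.86), COL21A1 at 4.12 against 14.7 (-1.61) and VCAM1 at 4.72 against 14.9 (-1.48). Part of the genes named by the rule also differed between the GFP and Ctrl libraries of NPSCs: ANKRD1 was 1.96 from GFP and 1.05 from Ctrl, and the chemokine gene CXCL2 -1.39 from GFP and -0.35 from Ctrl. Inflammatory genes had a median of -0.38 with 5 of 31 at least 1 lower, interferon genes of -0.24 and fibrillar genes of -0.16 with 3 of 36 at least 1 lower and 0 higher, each at percentile 0, the fibrillar list opposite to IPFSCs. The YAP list had a median of 0.12 at percentile 100. The GFP and Ctrl libraries also differed in these lists, with medians of GFP minus Ctrl of 0.16 (inflammatory), 0.18 (interferon), 0.06 (fibrillar) and -0.06 (YAP). Part of each shift could therefore lie in the GFP library, though 1 library of each does not tell which of them deviates. The cell cycle list had -0.03, which turned to 0.01 with median-ratio scaling, and its GFP minus Ctrl median was -0.31, so its value depends on the control. HOX genes of paralog groups 1 to 8 also lay at percentile 0 in OE minus GFP (median -0.24). Nucleus pulposus and notochord markers (median -0.20) lay at percentile 0.2 and p53 targets (median -0.12) at 0.3. TGF-beta and BMP genes (median 0.1) and pericyte and smooth muscle markers (median 0.16) lay at percentile 100.

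**Figure D3:**
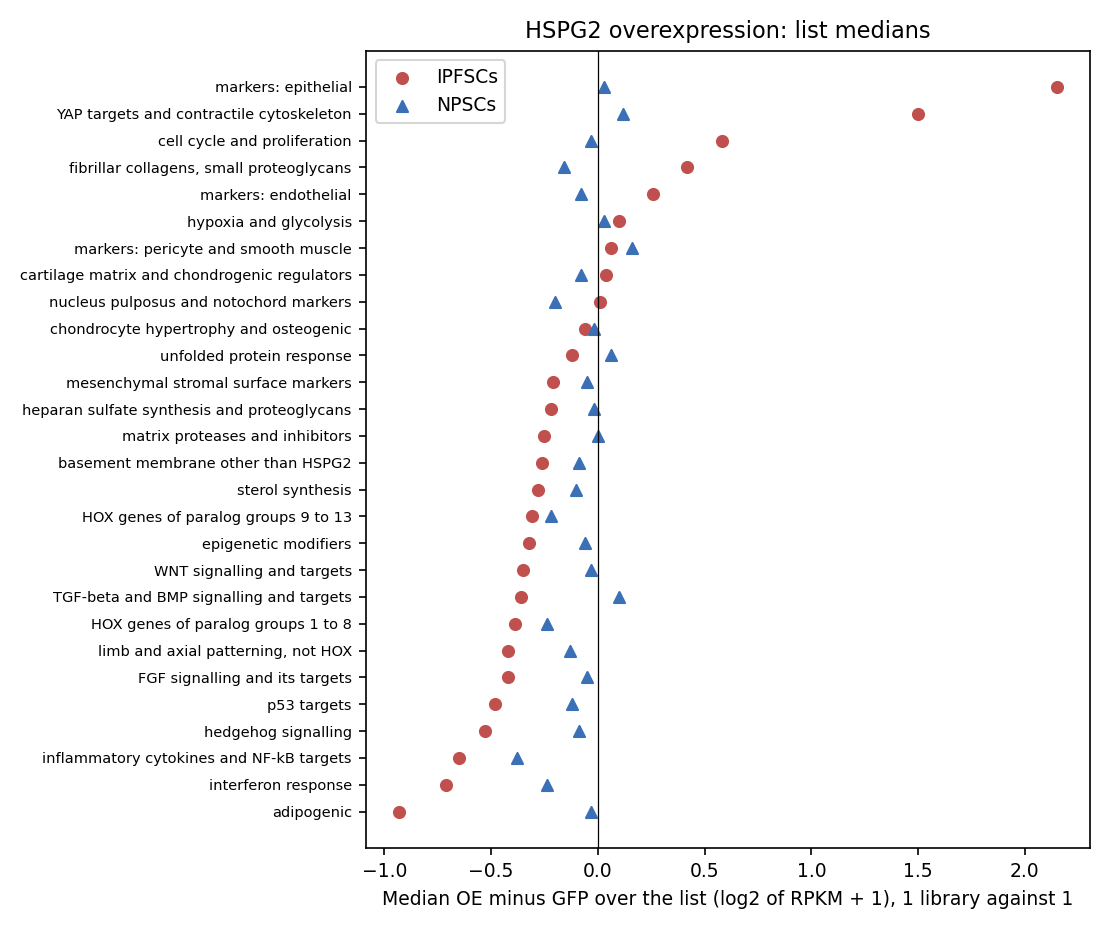
Median OE minus GFP difference (log2 of RPKM + 1) of each gene list, circles for IPFSCs and triangles for NPSCs, 1 library against 1 in each. The YAP list lies at 1.5 in IPFSCs and 0.12 in NPSCs, the interferon list at -0.71 and -0.24, and the hypertrophy list near 0 in both cell types, where it changed sign with median-ratio scaling.

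Across genes, which are not independent replicates, the OE effects of the cell types had an r of 0.37 (rho 0.40), again with no library shared. Within IPFSCs the KO effect from GFP and the OE effect from Ctrl had an r of 0.19, and KO from Ctrl with OE from GFP an r of 0.29. In NPSCs these were 0.30 and 0.06. The GFP minus Ctrl differences of the cell types had an r of -0.04.

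The GFP virus was compared with no virus as the background of transduction. The growth factor gene GDF5 (0.30, SE 0.07), the interferon-induced USP18 (0.41, SE 0.13), trnI (-0.77, SE 0.18) and the DNA repair gene RAD54L (-0.30) did not pass (adjusted p = 1). No gene passed in limma (0), 41 had an unadjusted p under 0.05, and voom called 0. Interferon genes passed camera upward (median 0.12, adjusted p = 4e-05) and cell cycle genes downward (median -0.09, adjusted p = 0.0023), both with adjusted p = 0.94 with an estimated correlation. The cell cycle shift was not shared, with a median of 0.15 in IPFSCs and -0.31 in NPSCs, and the interferon medians were 0.04 and 0.18.

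The first principal component took 84.2% of the variance and the second 12.4%. The 5 NPSC libraries lay between 46.7 and 51.7 on the first component and 4 IPFSC libraries between -62.7 and -55.4, with the IPFSC OE library at -7 and at -59.2 on the second. Its correlation with the other IPFSC libraries was 0.898 to 0.916 across genes, and with the NPSC libraries 0.898 to 0.905. POSTN, KRT18 and the YAP and inflammatory lists moved with that library in the comparisons above.

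**Figure D4:**
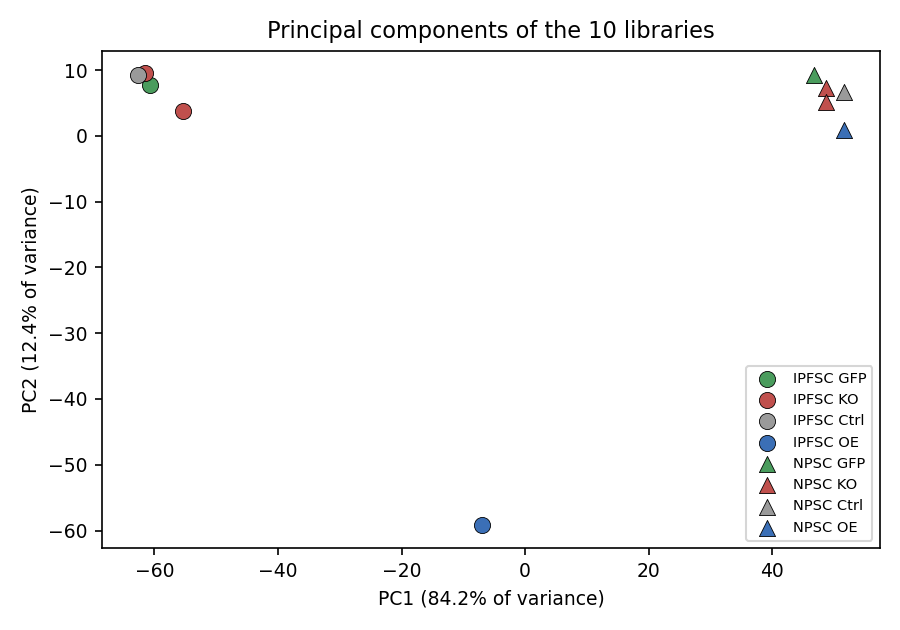
First and second principal component of the 10 libraries (log2 of RPKM + 1), circles for IPFSCs and triangles for NPSCs, coloured by treatment. The IPFSC OE library lies at -7 and -59.2, apart from both cell types.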

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

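Tests chosen only after the result was seen are those on the sign of the same genes in NPSCs, on the cell cycle list, on residual HSPG2, on the wider set of NPSC genes the simulation with 9 changed genes, and the gene-wise spread used in the simulations, which replaced a single spread.

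The IPFSC OE library lay far from the other 4 IPFSC libraries in 19 of the 27 measures compared among IPFSCs, and no NPSC library did in the measures compared among NPSCs. Most measures are genes named for the largest fold changes between the cell types in these same data. They move together, so the 19 are not separate observations and their number does not measure chance. The flagged measures were the first (-7) and second (-59.2) principal component, the share of reads in the top 10 genes (12.2%) and the levels of single genes. Genes higher there than in the other IPFSC libraries were CPA4 (RPKM 12.7), RGS4 (81.8), ACTG2 (0.481), CDH6 (0.678), KRT18 (113), COL11A1 (10.1), PSAT1 (82.7) and MFAP5 (579). Lower were CHI3L1 (435), PRG4 (44.5), CXCL6 (19.8), TRH (13.5), SERPING1 (37.3), FGF7 (16.4), PTGES (61.5) and SCARA5 (3.86).

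The tables argue against NPSC cells mixed into the IPFSC OE library: the 2 genes that were specific to NPSCs, ACTG2 and CPA4, stood at a median of 4.28% of their NPSC level there, while POSTN stood at 56.8% and KRT14 at 27400%. That planned test rests on 2 genes, and in a wider set of 11 genes the median was 18.7% with quartiles of 4.6% and 49.8%, where a mixture would give a common percent. Depth is also argued against, since thinning the IPFSC GFP reads to the depth of OE changed 0 genes by at least 1 in place of 1274. A response to HSPG2 that NPSCs share stays open: 80.2% of 837 genes had the same sign in NPSC OE minus GFP, but so had 77.5% in NPSC Ctrl minus GFP and 67.9% and 72.3% in the KO libraries minus GFP, and 69.9% in OE minus Ctrl, so the GFP library could give part of that share and HSPG2 and other differences between the NPSC libraries cannot be told apart. Another growth state of that culture stays open. The cell cycle list stood 0.58 above GFP where the other IPFSC libraries stood at -0.15 to -0.07. That value is part of the pattern itself, and the YAP (1.5), epithelial (2.15) and adipogenic (-0.93) lists moved further from GFP. It therefore does not single out growth state, and 1 library per cell type does not separate growth state from HSPG2.

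Few genes other than HSPG2 passed the KO tests. The planned simulation called 85.1% of 2-fold changes in IPFSCs with 200 changed genes, and the one with 9 called 25%. For KO in both cell types the planned share was 56.7%, or 98.5% with the OE libraries simulated at the control level, and for the KO difference 40.3%, so whether too little power is the cause cannot be told apart from a small effect, as it depends on how many genes change. Residual HSPG2 stays open as a cause: its transcript remained at 30% of GFP or more in each of the 4 KO libraries. This test was chosen after these levels were seen, and reads do not tell an intact transcript from a disrupted one. It therefore cannot decide the question, and how much protein remained was not measured.

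P4HA3 moved opposite ways in the cell types in both KO libraries of each, NPSC minus IPFSC -1.35, as did MFAP4 (-0.77) and SFRP4 (1.01). Both KO libraries of a cell type are set against the same GFP library, so they are not independent. P4HA3 was low in NPSCs: its mean RPKM over both cell types was 20 in KO and 10.1 in GFP, against 38.7 and 18.3 in IPFSCs alone. The test of that difference in limma passed for none of the 3 (adjusted p = 0.297, 0.385 and 0.481).

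OE minus GFP had opposite signs in the cell types, by more than GFP and Ctrl differed, for 10 of the named genes. Each value is 1 library against 1, and the difference was not tested. NPSC minus IPFSC was -5.92 for POSTN, -4.92 for F3, -4.74 for KRT18, -4.29 for ASPN, 1.37 for RELN, 1.96 for trnK, 5.22 for ISM1, 5.28 for PDK4, 5.74 for STMN2 and 6.22 for SFRP1. The largest of these differences lay mostly in IPFSCs, where OE minus GFP was 5.45 for POSTN, 4.28 for F3 and 4.49 for KRT18. There it was -5.03 for ISM1, -5.23 for PDK4, -5.70 for STMN2 and -5.18 for SFRP1. For these genes the NPSC shift was the smaller part, so the opposite sign does not show a strong opposite response. In NPSCs the levels of PDK4, ISM1 and STMN2 were under 1 RPKM.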

How the results depend on the processing

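The alternatives with voom, the list tests without the IPFSC OE library and the second settings of the single-library differences were chosen only after the data were seen. For the genes named by the rule, 115 of 9567 values under an alternative changed sign. Among those named in the text, this was HSPG2 in NPSC against IPFSC alone (-0.08, then 0.03 without IPFSC OE or without NPSC OE; the values range from -0.15 to 0.03 without each library). NPSC against IPFSC called 7159 to 9757 genes without each library in turn and stayed within 1.5 times under the other settings.

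Causes were not tested, apart from a simulation of KO in both cell types, where 2-fold changes were called in 56.7% with the OE libraries as measured and in 98.5% with these at the control level. KO against GFP in both cell types (0 genes) gave 1 with the mean of GFP and Ctrl, 2 with the group fit and 0 to 1 without each library. KO in IPFSCs (4 genes) gave 2 with a pseudocount of 0.1 (P4HA3 lost, adjusted p = 0.105), 1 without the filter (HSPG2 0.176, MEST 0.122 and P4HA3 0.166 lost), 1 without the intensity trend (0.0676, 0.11 and 0.104), 19 with the mean control, 18 with 2 control libraries, 40 with voom and 0 to 42 without each library. KO in NPSCs (0) gave 3 with a pseudocount of 0.1, 1 with median-ratio scaling, 5 with the mean control, 1 with voom and 0 to 2 without each library. The KO difference between cell types stayed at 0 under all settings run. OE against GFP in both cell types (0) gave 6059 with the group fit, 325 with voom and 0 to 7793 without each library. GFP against Ctrl (0) gave 1 without the filter, SPINK7. Leaving out a KO or OE library leaves 1 in that cell type or arm, assumed to vary like the others. The same holds for OE and GFP in the group fit, with 1 library of each per cell type and a spread from the KO pairs alone. KO within a cell type cannot be estimated without that cell type's GFP library, nor the difference without either.

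With a replicate block on the number in KO1 and KO2, KO in IPFSCs gave 20 genes, KO in NPSCs 4, NPSC against IPFSC 7751, and the other comparisons 0. The numbers are not shown to pair libraries: the replicate 2 minus 1 differences of the cell types had an r of 0.01 across genes.

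Of the gene lists past camera (13 for NPSC against IPFSC, 2 for KO in both, 3 for KO in IPFSCs, 3 in NPSCs, 4 for the difference, 3 for OE and 2 for GFP), 0 remained past the threshold with an estimated correlation in each comparison. That form has little power here: the cell cycle list, with 40 of 40 genes higher in NPSCs, had a camera adjusted p of 0.28 with it. It cannot tell which lists are robust. Without the IPFSC OE library, which leaves 1 OE library, the OE lists were 6 and not the same: cell cycle genes no longer passed and other lists did. The KO correlation between cell types was 0.04 with Ctrl as control in place of 0.12. HSPG2 lay below both controls in KO and above both in OE in 6 of 6 libraries with median-ratio scaling too. The total counts of 1274 and 33 genes stayed within 1.5 times with a pseudocount of 0.1 and with that scaling, while against Ctrl they were 1360 and 20. This holds for the totals only: the median over all genes of IPFSC OE minus GFP moved from -0.18 to -0.04 with that scaling, so the split into higher and lower genes may change. Depth limits low genes such as TRU-TCA2-1, called from 2 reads in IPFSC GFP.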

Other observations

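The tests chosen only after the result was seen are the correlations of the replicate differences other than that of IPFSC KO replicate 2 minus replicate 1 with IPFSC OE minus GFP.

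Several gene groups not described above had single genes that differed between NPSCs and IPFSCs, where 8168 of all 11894 genes tested passed. For epigenetic modifiers and heparan sulfate genes, the share of called genes was no higher than over all genes. Of 46 epigenetic modifiers, 21 were higher in NPSCs and 10 lower, with the DNA methylation maintenance factor UHRF1 at 2.32 (SE 0.11), the histone methyltransferase EZH2 at 2.05 (SE 0.06) and CBX7 at -1.85 (SE 0.18), and the list did not pass camera (adjusted p = 0.21). Of 26 heparan sulfate synthesis and proteoglycan genes, 11 were lower and 6 higher (adjusted p = 0.14), with the sulfatase gene SULF2 at -3.49 and the syndecan gene SDC2 at 2.01. TGF-beta and BMP genes were mostly lower, 16 of 28 against 7 higher, BMP6 at -4.33 and TGFB2 at 2.99 (adjusted p = 0.017, and adjusted p = 0.25 with an estimated correlation). WNT genes had 11 of 16 lower and 3 higher, LGR4 at -2.65 (adjusted p = 0.014, and adjusted p = 0.25 with an estimated correlation).

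Mesenchymal surface markers had 12 of 20 lower in NPSCs and 5 higher (adjusted p = 0.01, and adjusted p = 0.23 with an estimated correlation), with DPP4 at -4.10 and the perivascular marker gene MCAM at 3.54. Limb and axial patterning genes other than HOX had 16 of 30 lower and 9 higher, TBX15 at -3.97 and SHOX2 at -3.67 (adjusted p = 0.021, and adjusted p = 0.36 with an estimated correlation). Unfolded protein response genes had 11 of 26 higher and 5 lower, with the asparagine synthetase gene ASNS at 3.33 (adjusted p = 0.26). Hypoxia and glycolysis genes split 12 to 11 of 27 (adjusted p = 0.96), with a median of 0.22 and a mean of -0.10.

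Of 100 drawn splits of the 10 libraries into 5 and 5, 1 gave as many genes as the real split, which was the real one (8168). The highest of the others gave 4834. Libraries of a cell type resemble each other, so splits that mix the cell types were bound to call fewer genes. The number of donors is not given, so these splits cannot exclude a chance difference between donors or cultures.

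IPFSC KO replicate 2 lay nearer to the IPFSC OE library (r = 0.916) than replicate 1 did (r = 0.900). OE cells mixed into replicate 2 are argued against: 26 genes nearly specific to OE gained a median of 1.6% of their OE level (quartiles 1% and 3.1%), while 43 genes nearly lost in OE were lower by a median of 21.3% (quartiles 11.9% and 32.9%), where a mixture would give equal percents. A shared axis of culture state stays open: the r of 0.40 across genes between replicate 2 minus replicate 1 and OE minus GFP in IPFSCs restates that replicate 2 is the nearer one. With OE minus GFP in NPSCs the r was 0.16, and for the replicate difference of NPSCs with OE minus GFP in IPFSCs it was 0.09. The genes called without replicate 1, such as POSTN (1.56), F3 (1.19) and CXCL8 (1.46), rest on replicate 2 alone.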
